A study of Arabidopsis thaliana with 5 samples.

How the data were processed

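The study as labelled holds 5 libraries, 2 from roots expressing the BLJ fusion, 2 from roots expressing the JKD fusion and 1 from wild-type roots. Per the labels' protocols, immunoprecipitated DNA was linearly amplified, fragmented and tagged by transposon insertion (Nextera), and sequenced as single-end reads of 50 bp. Per the submitters' processing notes, CASAVA and Bowtie were used and the genome build was TAIR9, with no versions. The peak caller, the way replicates were combined, the normalization of the density signal and the use of the control are not given in the sources used here. Per the labels' protocols the libraries were pooled in 1 lane, while the deposited sample sheets list replicate 1 of each factor and the control in lane 5 of a first flow cell and replicate 2 of each factor in lane 2 of a second.

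The authors deposited 1 table of regions per factor, called on both replicates together. Per the file headers each region has a chromosome, a start, an end, a length, a summit, a density signal for the replicates and an IDR value. Length equals end minus start plus 1 in every region, so coordinates are 1-based and inclusive, and the summit equals the rounded-down middle of the region in every region, so it adds nothing to the midpoint. The density cell holds 2 positive numbers, called here the first-listed and second-listed value, since no source says which replicate each is. The deposited IDR is the authors' measure of reproducibility between replicates, read like a p-value or q-value from 0 to 1, and was used only to rank or restrict regions within a list. The deposited density signal is the authors' own value per region, and was compared only within a list, because the normalization that would allow a comparison between lists is not given. The score of a region is the mean of the log2 of both values.

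Gene names, classes and neighbours came from an NCBI gene table of assembly TAIR10.1, which gives no strand, no exons and no sequence. It holds 27444 protein-coding genes on the nuclear chromosomes. The nuclear chromosomes of TAIR9 and TAIR10 are the same assembly, and this was checked on the regions. For genes of at least 2000 bp, the rise in cover across the gene edge was steepest at an offset of -100 to 100 bp (median 0) in all 30 parts tested, of offsets up to 3000 bp in steps of 100 bp. All printed coordinates are those of the deposited regions on TAIR9. Without strand, the planned windows around transcription start sites were replaced: a gene counted as near a region if the region overlapped the gene or the 1000 bp on either side of it by at least 1 bp, and the planned promoter share was replaced by the share of region midpoints inside protein-coding genes. Searches for the binding motif of IDD proteins were not run, because no genome sequence was used here.

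Named genes followed a rule fixed before the data were examined: every member of the IDD family and ground tissue lists, the gene nearest to each of the 10 highest regions of each factor, the 10 genes with the smallest sum of score ranks, the 5 genes of highest score near 1 factor only per factor, and up to 4 members of highest score from each other list. The 22 lists were fixed by then as well. They hold IDD genes, ground tissue regulators, markers of endodermis barrier, quiescent centre and stem cells, epidermis and root hairs, stele, and root cap, genes of auxin, gibberellin and the cell cycle, the comparison lists photosynthesis and ribosomal proteins, and 10 transcription factor families taken from gene symbols and products, of which 9 are described here (MYB, WRKY, NAC, bHLH, AP2/ERF, homeobox, GRAS, C2H2 zinc finger and bZIP), which therefore miss family members with other symbols and hold some genes of other kinds under like names, such as 3 release factors and 2 E3 ligases in the AP2/ERF list. The ribosomal list holds 7 organellar proteins. All members of the lists were found in the gene table. For each gene the region of highest score within 1000 bp was taken. AT1G14580 has no symbol in that table.

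Overlap of the lists and location in genes were tested against 10000 random rotations of a list along each chromosome (two-sided permutation tests). Genes near both factors and gene lists were tested with two-sided Fisher's exact tests, and lists also against 10000 random lists matched on gene length in 10 bins. Differences between factors per list were tested with exact McNemar tests. Shared and factor-only densities were compared with 100000 permutations of the difference in medians. Benjamini-Hochberg adjustment covered 22 lists and both factors. Shares carry 95% Wilson intervals, which cover counting error only, and correlations across regions carry 95% intervals from 1000 bootstraps. Wide blocks were runs of windows of 40000 bp, moved in steps of 1000 bp, covered to at least 90%. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

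The rotation test of overlap, the exact tests of gene lists, the permutation test of density and the block search were tested on simulated data. The other tests were not. Rotation, density and blocks were simulated from real regions, with rotation and density at 200 resamples only. For density, which regions counted as shared was drawn at random. Gene lists kept only the real number of genes, with members drawn singly, so gene position, gene length and real list sizes were not kept. The rates below hold for these settings. Over 100 runs of the rotation test with 24229 regions, unrelated lists were called in 2 runs, a planted overlap of 10% of regions in 28 and one of 30% in 100, the larger size having been added after the smaller was seen to be called seldom. A planted list of low share was called in 90 of 100 runs over 27444 genes, and unchanged lists in 0.333% of 2100. No list of higher share was planted. A planted density difference of 0.05 was called in 100 of 100 runs and no difference in 4. All 20 planted blocks were found, but each was planted as a single unbroken region, so this outcome was fixed in advance. False calls of the block search were not measured.

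The alternatives were the denser 50% of each list, merging of regions under 200 bp apart, an overlap of 50% of both regions, midpoints within 500 bp, means in place of medians, removal of the top 1% of regions and each density value alone. Added after seeing the data were IDR limits of 0.1 and 0.05, removal of regions over pseudogenes, removal of the wide blocks, local shifts of 5000 to 50000 bp, other gene rules, lists without genes of other kinds or organellar ribosomal proteins, density relative to regions of like width and length strata.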

Results

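Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where BLUEJAY (BLJ) and JACKDAW (JKD) sit on the Arabidopsis thaliana genome. Both are C2H2 zinc finger transcription factors of the INDETERMINATE DOMAIN (IDD) family that act in the ground tissue of the root, the layers that form cortex and endodermis. Whole roots of Columbia plants carrying either factor fused to yellow fluorescent protein were fixed, and an antibody against GFP, which also binds the yellow variant, recovered the fusion protein with its DNA. The samples comprised 2 BLJ libraries, 2 JKD libraries and 1 wild-type library. For each factor a single list of bound regions was analysed, made from both of its replicates together. The BLJ list held 24229 regions covering 31.7 Mb with a median width of 1015 bp, and the JKD list held 21985 regions covering 27.0 Mb with a median width of 906 bp. Each region carried 2 density values, 1 per replicate in an order that the sources used here do not give, and an irreproducible discovery rate (IDR). Median densities were 1.60 for the first-listed and 1.38 for the second-listed value in the BLJ list, and 1.10 and 1.49 in the JKD list. Read depth per library is unknown, and no control table was analysed here, so no value below has a wild-type background beside it. Density was compared only within a list. The regions give no error per replicate for shares and counts, so their intervals cover counting error only.

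The region lists were unlike the rest of the genome at the factors' own genes. Around AT1G14580, the gene entered as BLJ, 7 regions of the BLJ list covered 94.7% of a block of 70.6 kb (TAIR9 chromosome 1, 4956801 to 5027368), which spans 19 protein-coding genes. Across the whole genome the BLJ list covered 26.6%. Mean densities in this block were 1.95 times the genome-wide mean for the first-listed value and 1.83 times for the second-listed value. Around JKD (AT5G03150), 9 regions of the JKD list covered 89.7% of a block of 57.0 kb on chromosome 5 (716660 to 773689), at 1.56 and 1.33 times the genome-wide means. A further block of the JKD list, 78.6 kb long with 25 genes, lay on chromosome 1 (951059 to 1029648) at MAGPIE (MGP, AT1G03840), another IDD gene, with 96.8% cover and densities of 1.88 and 3.20 times the genome-wide means. The list of the other factor had more cover in these blocks than its genome-wide 22.6% (JKD) or 26.6% (BLJ), without the raised density. JKD regions covered 34.7% of the block at AT1G14580 with a mean density of 0.954 times the genome-wide value (746 of 3369 windows of that length were covered as much), and BLJ regions covered 42.7% of the block at JKD with 1.08 times (718 of 4169 windows). At MGP, BLJ regions covered 52.1% with 1.02 times (138 of 3024 windows). In the 20000 bp on either side of these 3 blocks, density of the list concerned was between 0.875 and 1.07 times the genome-wide value. Ends set by cover can lie beyond a decline, as at JKD, where the first-listed density was 2.10 in the widest region and 1.13 and 1.15 in the outermost. The blocks were defined by cover alone, as windows of 40000 bp covered to at least 90%, and this search was added after the lists had been seen.

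**Figure D1:**
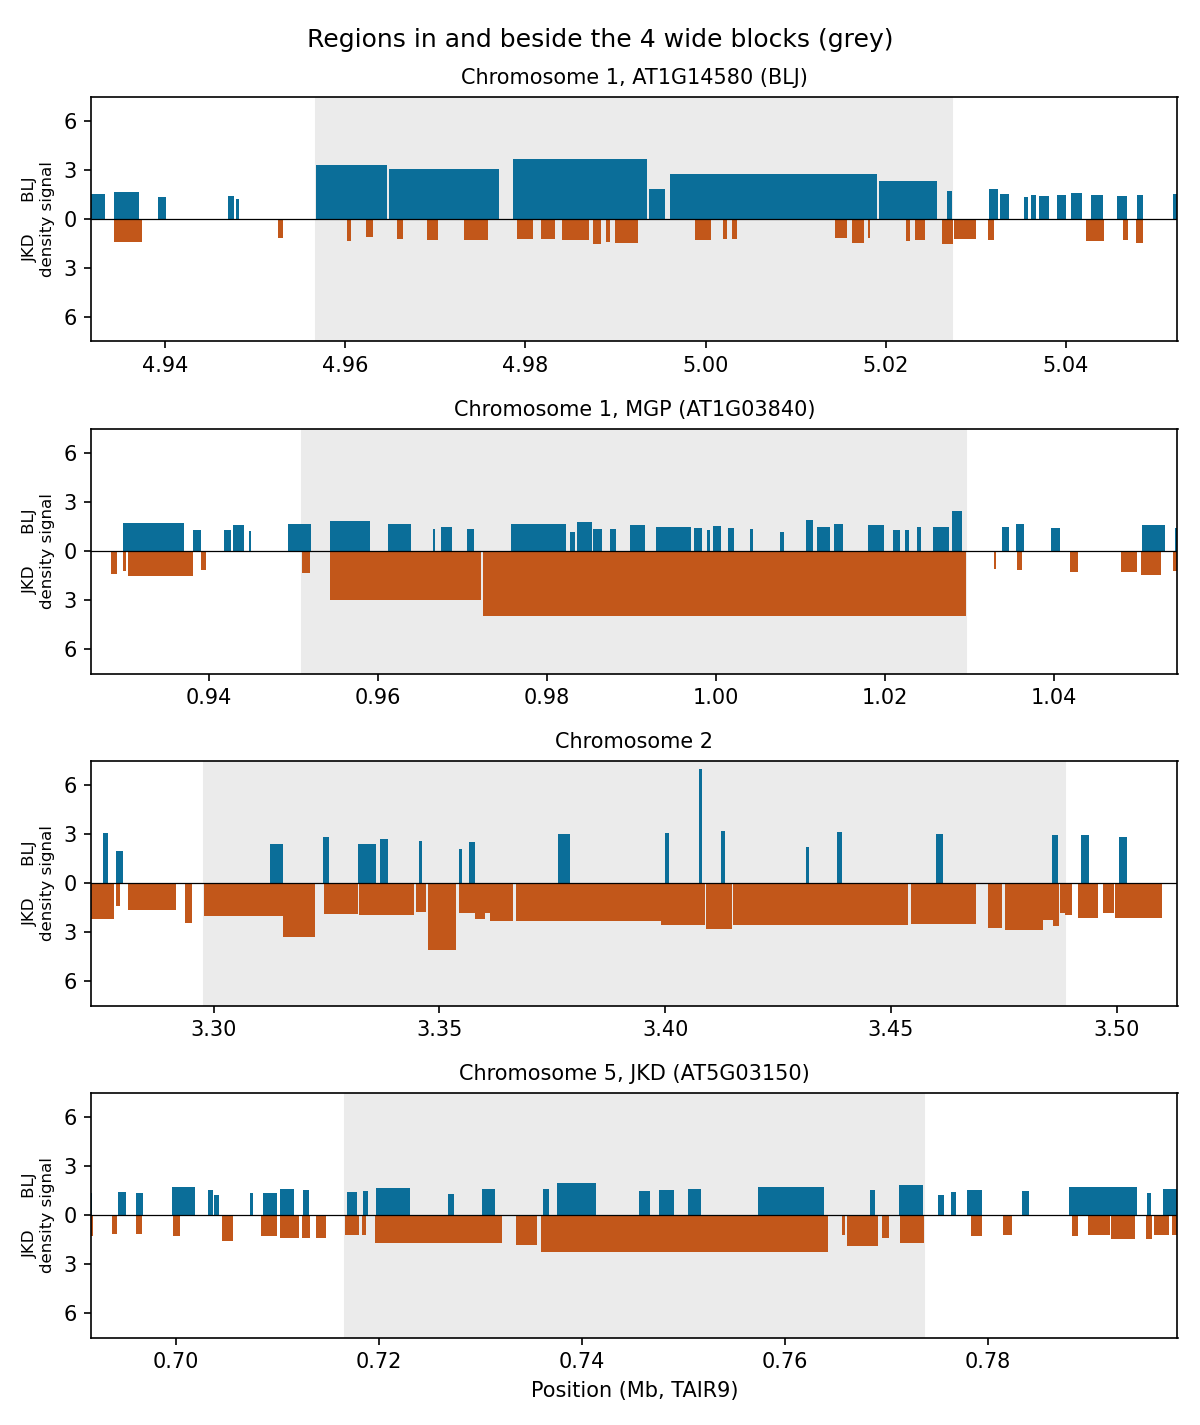
Regions of both lists around the 4 wide blocks found by cover, plotted by position on TAIR9 (Mb, horizontal axis). Each bar is 1 region, its height the mean of its 2 density values (vertical axis), upward for BLJ and downward for JKD, and grey shading marks the block. The BLJ list stands out at AT1G14580 with 94.7% cover, and the JKD list at JKD and MGP with 89.7% and 96.8%.

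Genes that pattern the ground tissue carried regions of both factors. Of 13 ground tissue regulators fixed before the data were examined, 12 lay within 1000 bp of a BLJ region and all 13 within 1000 bp of a JKD region. SCARECROW (SCR, AT3G54220), a GRAS transcription factor needed for the division that separates cortex from endodermis, was overlapped by a BLJ region on chromosome 3 (20068833 to 20072520, densities 1.85 and 1.74, IDR 0.066) and a JKD region (20068816 to 20071966, densities 1.21 and 1.93, IDR 0.0142). SHORT-ROOT (SHR, AT4G37650), the mobile GRAS factor that acts with SCR, was overlapped by regions on chromosome 4, at 17691984 to 17693503 for BLJ (densities 1.54 and 1.39, IDR 0.0456) and 17691187 to 17693432 for JKD (densities 1.15 and 1.86, IDR 0.0398). At CYCD6;1 (AT4G03270), the D-type cyclin of that division, a JKD region overlapped the gene (1426996 to 1432886 on chromosome 4, IDR 0.181), and a BLJ region (1426706 to 1431829, IDR 0.0473) ended 15 bp from it. Regions of both factors also overlapped RBR1 (AT3G12280), the retinoblastoma homologue, MYB36 (AT5G57620), an activator of Casparian strip genes, and NUTCRACKER (NUC, AT5G44160). Of the 13 regulators, 11 were overlapped by regions of both factors, and the other 2 by a JKD region alone. HSFB4 (AT1G46264), known as SCHIZORIZA, had a JKD region with an IDR of 0.20 and no BLJ region within 1000 bp.

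Most of the IDD family was listed for both factors. Of 16 members, 15 lay near a BLJ region and 12 near a JKD region. IDD12, IDD14 and IDD15 had a BLJ region and no JKD region, and AT5G60470, entered as IDD13, had neither. Regions beside IDD1 (AT5G66730) on chromosome 5 ranked high in both lists. The BLJ region (26644833 to 26645629, densities 1.70 and 2.28) had a density percentile of 96.7 in its list and the JKD region (26644793 to 26646360, densities 1.5 and 1.94) one of 98.2. These counts did not separate the groups from other genes, because 80.8% of all 27444 protein-coding genes lay near a BLJ region and 76.8% near a JKD region. Fisher's exact test gave an adjusted p of 0.593 and 1.00 for the IDD family and 0.740 and 0.218 for the ground tissue regulators, BLJ and JKD in that order. Where regions were restricted to an IDR at or below 0.05, 5 of the 13 regulators had a BLJ region and 6 a JKD region, SCR and SHR among both, although the BLJ region given above for SCR did not pass and a second region near the gene did. At that limit 11.2% of all genes lay near a BLJ region and 22.2% near a JKD region, and the regulators passed adjustment for neither factor. In the BLJ list a low IDR hardly went with a high density. There the Spearman correlation of IDR was 0.064 with the first-listed and -0.146 with the second-listed value. In the JKD list these were -0.629 and -0.502, so a limit on IDR does not select alike in both lists. The JKD and MGP genes and AT1G14580 lie inside the wide blocks, whose densities do not stand for single sites. Block regions of low IDR place AT1G14580 among the 5 (IDR 0.00449) and JKD and MGP among the 6 (0.000913 and 0.00028).

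The genes with the highest density in both lists included CZF1, ERF4, CAF1a and WRKY47. The smallest sum of density ranks belonged to CZF1 (AT2G40140), which encodes a CCCH zinc finger protein. Its regions on chromosome 2 spanned 16771997 to 16774688 for BLJ (densities 2.23 and 5.08) and 16771913 to 16774691 for JKD (1.21 and 4.14). The same regions reached within 736 bp and 733 bp of TBL28. ERF4 (AT3G15210), an ethylene response factor, followed with densities of 2.00 and 4.08 for BLJ on chromosome 3 (5121101 to 5126185) and 1.46 and 3.92 for JKD (5121102 to 5126540). CAF1a (AT3G44260), a deadenylase, had 2.12 and 3.60 for BLJ and 1.45 and 4.43 for JKD. Beside WRKY47 (AT4G01720), regions on chromosome 4 held 2.68 and 3.0 for BLJ (743745 to 744673) and 2.08 and 2.90 for JKD (743781 to 744513). AT3G15220, AT4G37685 and AT4G37690 shared regions with their neighbours, and AT2G07714 and AT2G07646 lie in a stretch of chromosome 2 described among the other observations. Among genes near 1 factor only, the highest BLJ densities outside the wide blocks were 6.44 and 1.5 at AT2G03965, 4.32 and 1.95 beside SUF4 (AT1G30970) and 5.90 and 1.38 at AT5G53710. The highest JKD densities outside the blocks were 1.09 and 7.48 beside AT1G31255, with an IDR of 0.315.

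Of the 10 highest BLJ regions, some lay away from protein-coding genes. The highest, on chromosome 3 (11686244 to 11686471, densities 14.6 and 7.19, IDR 0.0025), overlapped a pseudogene and had its midpoint 6737 bp from the nearest protein-coding gene, AT3G29790. The third highest (13185528 to 13186025, densities 7.26 and 3.61) lay 14250 bp from AT3G32200. The second highest (densities 4.87 and 9.05) lay in AT2G07714 on chromosome 2, inside the block of the JKD list there. A region whose midpoint lay 2319 bp from PP2CA (AT3G11410), a protein phosphatase of abscisic acid signalling, overlapped non-coding RNA genes and had a density of 13.6 in the first-listed and 1.29 in the second-listed value, with an IDR of 0.299. Among the 10 highest JKD regions outside the blocks were those at AT4G00893 (densities 1.85 and 4.21), CRK22 (AT4G23300, 1.35 and 5.70), AT2G25460 (1.70 and 3.88) and a region 2586 bp from MYB73 (AT4G37260, 1.93 and 3.35).

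No list of root genes fixed before the data were examined passed the test against other genes. All 16 endodermis barrier genes lay near a BLJ region and 14 near a JKD region. ESB1 (AT2G28670), a dirigent-like protein of the Casparian strip, had BLJ densities of 3.42 and 1.64 and JKD densities of 1.10 and 1.67, and ASFT and AT1G61590, entered as SGN1, were among the next in the BLJ list. Of 14 quiescent centre and stem cell genes, 10 lay near a BLJ region and 10 near a JKD region, with CLV1, PLT7 and ACR4 among those near both, WOX5, PLT3 and ERF115 near BLJ regions alone, and PLT2, BBM and PLT5 near JKD regions alone. Of 16 epidermis and root hair genes, 11 were near a region of each factor, and WER, MYB23, RSL1 and RSL2 were near neither. For the stele the counts were 11 and 9 of 13, with SUC2, AHK4, TMO5 and ATHB8 the densest in the BLJ list. For the root cap they were 1 and 2 of 4, with BRN1 near both, FEZ near JKD alone, and SMB and BRN2 near neither. Auxin genes gave 16 and 18 of 19, gibberellin genes 19 and 18 of 20 and cell cycle genes 19 and 18 of 20, BLJ and JKD in that order. PIN3 (AT1G70940), an auxin efflux carrier, had density percentiles of 98.4 and 99.7. GA3OX2 (AT1G80340), an enzyme of gibberellin synthesis, had BLJ densities of 3.19 and 1.67, and SIM (AT5G04470), an inhibitor of cyclin-dependent kinases, had 4.96 and 2.08. The comparison lists gave 36 and 34 of 45 for photosynthesis genes and 39 and 36 of 42 for ribosomal proteins. None of these lists, nor the IDD and ground tissue lists, passed adjustment over 22 lists and both factors. Small lists left little room to show a higher share, since 80.8% of all genes lay near a BLJ region and 76.8% near a JKD region. Even with all 16 members near a BLJ region, the endodermis barrier list did not pass. Not passing therefore does not show that a list was covered as often as other genes. Among all 22 lists, an unadjusted p under 0.05 was reached by 4 lists for BLJ and 5 for JKD.

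Of the transcription factor families, 9 are described here and none of these passed the test with the full lists. Of all 22 lists, 1 passed for each factor and is not described here. BLJ and JKD counts were 95 and 90 of 132 for MYB (exact test, adjusted p = 0.210 and 0.214), 62 and 63 of 72 for WRKY, 84 and 79 of 104 for NAC, 20 and 19 of 24 for bHLH, 37 and 35 of 41 for AP2/ERF, 60 and 59 of 73 for homeobox, 18 and 15 of 19 for C2H2 zinc finger and 40 and 36 of 46 for bZIP genes. All 16 GRAS genes, the family of SHR and SCR, lay near regions of both factors (exact test, adjusted p = 0.218 for each). When only the denser 50% of each list was used, GRAS genes passed for both by the exact test, with 15 of 16 near BLJ (adjusted p = 0.0268) and 16 of 16 near JKD (adjusted p = 0.00104), but against random lists of like gene length for JKD alone (adjusted permutation p = 0.0729 and 0.0088). With that choice endodermis barrier genes (15 of 16, 93.8% against 57.6%) and AP2/ERF genes (33 of 41, 80.5%) passed for BLJ, each with an adjusted p of 0.0268 (0.037 and 0.0044 against lists of like length). WRKY genes (50 of 72, 69.4%) passed for JKD with an adjusted p of 0.0395 by the exact test, and did not pass against lists of like length (adjusted permutation p = 0.0997). With regions at an IDR at or below 0.05, GRAS and AP2/ERF genes passed for JKD, above other genes. They did so by the exact test and against lists of like length. At a limit of 0.1 both passed for JKD by the exact test, but only AP2/ERF against lists of like length. Neither passed for BLJ at these limits, where NAC genes passed at 0.1, below other genes. Both limits were added after seeing the data. For the full lists, the difference between factors was tested with exact McNemar tests on the genes near 1 factor only. Of these lists 0 of 22 passed, with 0 at an unadjusted p under 0.05. Lists with few such genes could not pass at any split, so their result was fixed in advance. Among them were the IDD family (3 genes near BLJ alone, 0 near JKD alone, exact McNemar p = 0.25), ground tissue regulators (0 and 1) and GRAS genes (0 and 0).

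**Figure D2:**
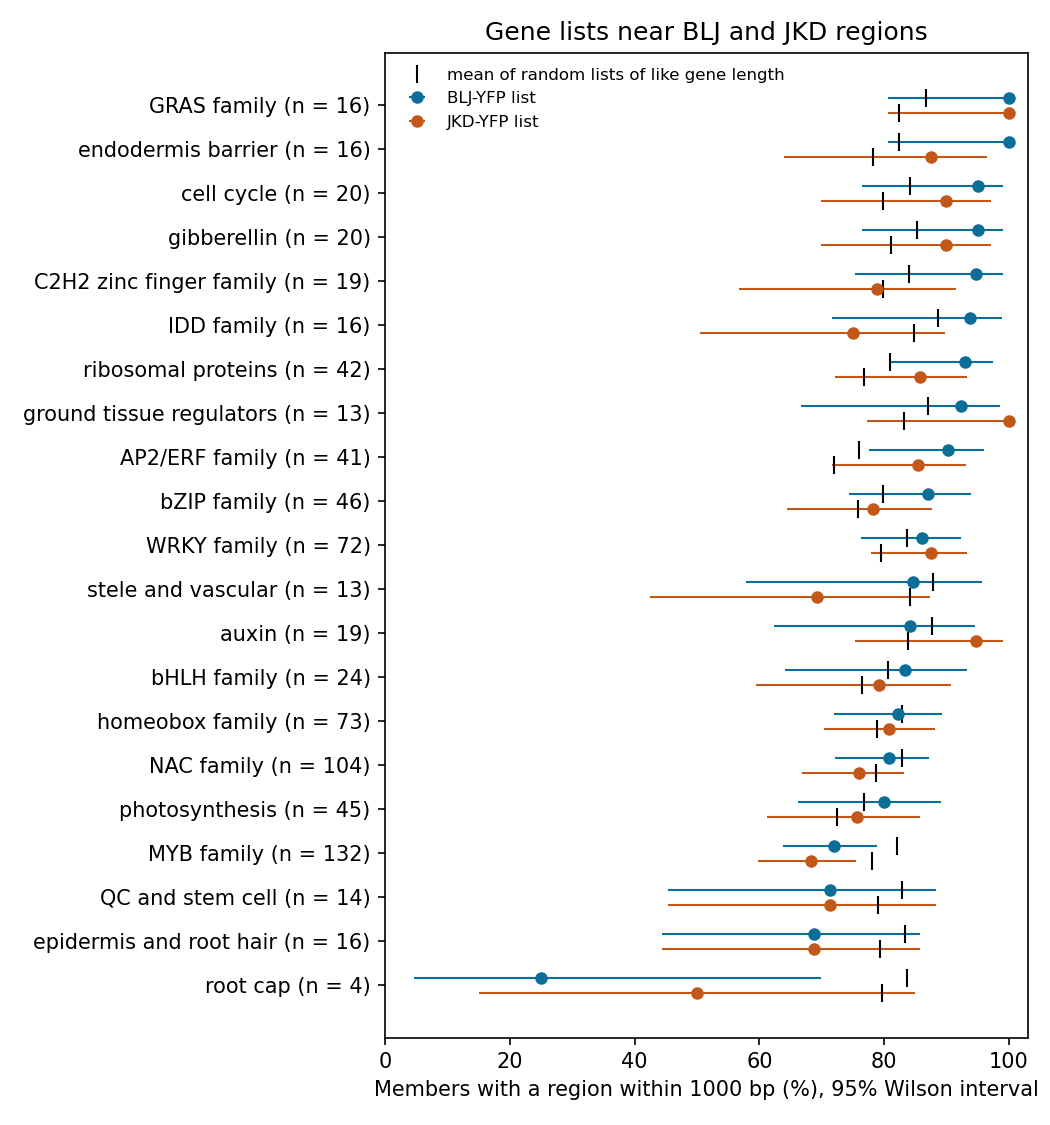
Share of each gene list with a region within 1000 bp (percent, horizontal axis) for BLJ and JKD, with 95% Wilson intervals. Black ticks mark the mean of random lists of like gene length. Of the 22 lists, 21 are drawn. All 16 GRAS genes lie near regions of both factors, and the MYB family lies below its ticks, with 95 and 90 of 132 genes.

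Density ranked the AP2/ERF list above other genes for both factors. The median density percentile of the strongest region near a family member was 88.3 over 37 genes for BLJ, where all genes near a region had a median of 68.5, and 92.3 over 35 genes for JKD, against 67.4. Both medians lay above 10000 random lists of the same size (permutation p = 0.0002, the smallest they can give, adjusted p = 0.0044). Random lists drew genes singly, while members that lie side by side, such as AT4G17490 and AT4G17500, can share a region. The list, drawn by name, held 5 genes of other kinds (3 release factors and 2 E3 ligases), and without them the medians were 88.8 over 32 genes and 94.3 over 30 (permutation, adjusted p = 0.0088 for both). ERF4, ERF104 (AT5G61600), ERF6 (AT4G17490) and ERF10 led the family, ERF10 inside the block at MGP. ERF104 had densities of 2.14 and 3.68 for BLJ and 1.5 and 3.33 for JKD, and ERF6 had 2.23 and 2.79 for BLJ and 1.45 and 2.62 for JKD. With the first-listed value alone the BLJ median was 65.0, close to the median of all genes, 65.6 (permutation, adjusted p = 0.983). For JKD it was 89.8 (permutation, adjusted p = 0.0088). WRKY genes, among them WRKY40, WRKY33 and WRKY17, had medians of 73.6 and 73.9 and did not pass (permutation, adjusted p = 0.612 and 0.481).

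The full lists shared most of their regions when 1 bp of overlap counted. Of BLJ regions, 16645 of 24229 (68.7%, 95% Wilson interval 68.1 to 69.3) overlapped a JKD region by at least 1 bp, and 16959 of 21985 JKD regions (77.1%, 76.6 to 77.7) overlapped a BLJ region. That was 1.72 and 1.77 times the mean after random rotation of a list along each chromosome, and no share exceeded 47.9% and 52.1% in 10000 rotations (permutation p = 0.0002, the smallest they can give). When 50% of both regions had to overlap, 10978 pairs remained (45.3% of BLJ and 49.9% of JKD regions), 4.98 times the mean of the rotations. With both lists restricted to an IDR at or below 0.1 the shares were 33.9% and 26.7%, and at or below 0.05 they were 22.6% and 11.5%, in shorter lists where rotations gave less overlap too (1.89 and 1.90, then 2.37 and 2.34 times their mean). For genes, 22170 lay near a BLJ region, 21082 near a JKD region and 19544 near both, where independent lists would give 17031. The log2 odds ratio was 4.18, and rotation of the gene order gave at most 17571 genes near both (permutation p = 0.0002). Restricting both lists to an IDR at or below 0.05 left 1037 genes near both and a log2 odds ratio of 0.96. The labels hold a single wild-type library, so a control shared by both lists is not excluded, and the lists are then not independent of each other.

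Regions of both factors lay mainly inside genes. The midpoint fell within a protein-coding gene for 83.4% of BLJ regions (95% Wilson interval 82.9 to 83.8) and 78.3% of JKD regions (77.7 to 78.8), where rotations gave 54.2% and 54.1% (permutation p = 0.0002 for both, the smallest they can give). Cover around gene ends was measured on genes of 4 kb or more. At 400 bp inside either gene end, 45.2% of ends were covered by a BLJ region and 35.9% by a JKD region, against 34.9% and 30.2% at 500 bp outside and 29.9% and 19.6% at 2000 bp inside. The start and the end of a gene were not told apart, as the gene table used gives no strand. The factors differed in the regions they did not share. Midpoints of BLJ-only regions lay within genes in 82.0% of 7584 cases (81.1 to 82.8) and those of JKD-only regions in 63.5% of 5026 cases (62.1 to 64.8), a log2 odds ratio of 1.39 (Fisher's exact test, p = 1.97e-119, over regions, which are not independent replicates). Shared regions had 84.0% and 82.7%.

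**Figure D3:**
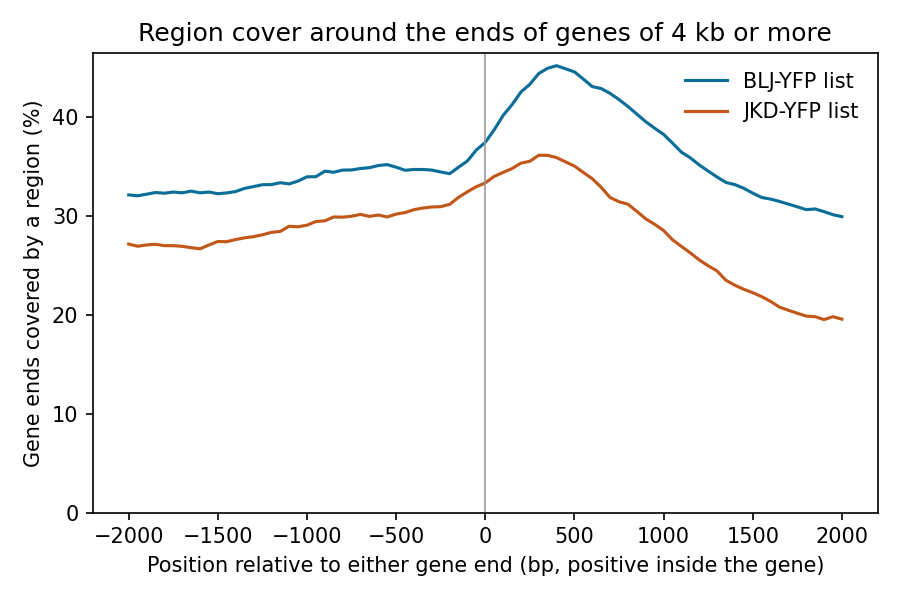
Percent of gene ends covered by a region (vertical axis) against position relative to either end in bp (horizontal axis, positive inside the gene), for genes of 4 kb or more, with 1 line for BLJ and 1 for JKD. Cover is higher just inside the gene than outside it, 45.2% for BLJ and 35.9% for JKD at 400 bp inside.

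Shared regions were slightly denser than regions of 1 factor only. They were also wider, which counting an overlap of 1 bp favours by construction. Median widths were 1230 bp for shared and 713 bp for BLJ-only regions in the BLJ list, and 1052 bp and 578 bp in the JKD list. The median log2 density of shared regions was higher by 0.12 in the BLJ list (8.56% higher) and by 0.06 in the JKD list (4.15% higher), each with p = 1e-05, the smallest that 100000 permutations can give. Relative to regions of like width the difference was 0.06 in the BLJ list and ended in the JKD list, at 0.000788 (permutation p = 0.687). JKD regions of low IDR were shared more often, 86.4% at an IDR at or below 0.05 and 70.1% above 0.2, but they were also wider (medians 1235 bp and 725 bp), while the BLJ list gave 66.2% and 67.0% (933 bp and 988 bp).

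The density values of a factor's 2 replicates agreed only in part. Across regions the Spearman correlation of first-listed and second-listed values was 0.248 in the BLJ list and 0.407 in the JKD list (Pearson 0.270 and 0.431), and regions are not independent replicates. An IDR at or below 0.05 was reached by 1990 BLJ regions (8.21%) and 3892 JKD regions (17.7%). Over the 10978 regions shared by 50% both ways, second-listed values correlated across the factors with 0.556 (95% bootstrap interval 0.543 to 0.570), above the 0.162 (0.143 to 0.183) within BLJ and the 0.40 (0.384 to 0.416) within JKD. First-listed values correlated across factors with 0.285 (0.267 to 0.301). The sample sheets place replicate 1 of both factors and the control on 1 flow cell and replicate 2 of both factors on another, so replicate and flow cell cannot be told apart.

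**Figure D4:**
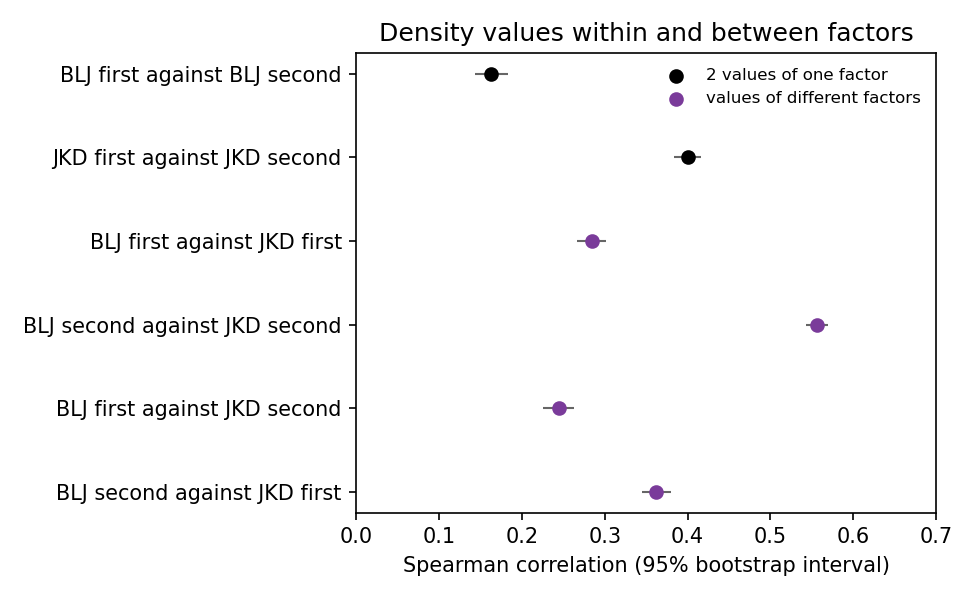
Spearman correlation (horizontal axis) of density values over the 10978 regions shared by 50% both ways, for each pair of values named on the vertical axis, with 95% bootstrap intervals. The second-listed values of the 2 factors correlate most, at 0.556, and the 2 values of BLJ least, at 0.162.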

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

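The tests of repeats, of a second construct, of block ends and of gene length and the comparison of factor-only regions were chosen after the results were seen, and those of the construct, local shifts, shared profiles and AP2/ERF density after the lists but before their own results. The location of factor-only regions differed between the factors by a test of the difference itself, with a log2 odds ratio of 1.39 (82.0% of BLJ-only and 63.5% of JKD-only midpoints inside protein-coding genes, Fisher's exact test, p = 1.97e-119). Over 8 other settings the log2 odds ratio ranged from 0.80 to 1.63.

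Wide blocks of dense regions lie at AT1G14580 in the BLJ list and at JKD and MGP in the JKD list. Reads piling up on repeats or a reference error would raise the list of the other factor too, and its mean density there reached at most 1.08 times its genome-wide value, which argues against that explanation, although its cover there was above its genome-wide value. Extra copies of the construct that carries the tagged gene stay open for the own-locus blocks. Density beside them was at most 1.01 times the genome-wide value, but block ends were set by cover, and the outermost regions inside differed. At AT1G14580 the first region stood at 2.10 times, with 0.875 times before it, a sharp end as such copies would give. The last stood at 1.07 times, and at JKD the outermost regions were at 0.891 and 1.18 times. Where the outermost region is already low, density beside a block decides nothing. A construct at MGP stays open too, with at most 1.07 times beside that block, and no label names one. The first region of that block was at 0.963 times, while the last was at 2.69 times, with 0.915 times after it, so its ends differed as well. No biological explanation was tested, and neither plasmid nor input reads were used here.

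The overlap of the lists exceeded that after rotation or local shifts. Gene length does not account for genes near both, since the log2 odds ratio within 10 length strata was 3.90. Shared gene-rich neighbourhoods do not account for the overlap of regions, since local shifts gave at most 50.5% of BLJ regions against 68.7% observed. Rotations and shifts do not keep regions inside genes, where 83.4% of BLJ and 78.3% of JKD midpoints lay (54.2% and 54.1% after rotation). Unrelated lists that each favour genes could exceed them too, so such a shared preference stays open for the overlap of regions. A density profile shared by libraries made or sequenced together is consistent with the second-listed values, which correlated across the factors with 0.556, above both correlations within a factor, while the first-listed values with 0.285 lay between those within BLJ (0.162) and JKD (0.40) and decide nothing. Values in different places correlated across the factors too, BLJ second with JKD first at 0.362, above 0.285, and BLJ first with JKD second at 0.245, so place alone does not order the correlations, and that values in the same place share a flow cell is not given in the sources used here. Binding of both related factors to the same sites stays open as a biological explanation, and a control comparison that could separate it was not analysed here.

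The dense regions at AP2/ERF genes were also tested. Width does not account for them, since among regions of like width the lower of the medians was at percentile 85.8 (BLJ, permutation, adjusted p = 0.0044). A response of the plants behind a single set of libraries could explain the BLJ list, where the median fell to 65.0 with the first-listed value, within random lists. The test as set beforehand asked for such a fall in both lists, and in the JKD list the first-listed value alone gave 89.8 (permutation, adjusted p = 0.0088), which argues against it for JKD and for both lists together. Binding by the factors themselves and open chromatin at these genes were not tested.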

How the results depend on the processing

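The tests with IDR limits, without pseudogene regions or wide blocks, with other gene rules, without list members of other kinds, and of like width or gene length were chosen after seeing the data. Of the values that answer a comparison, 83 were the same under an alternative, 11 counts of lists moved by over 1.5 times and 1 lost its call. For tests, the same meant an unchanged direction and side of the threshold. For counts of lists (7 for BLJ, 6 for JKD and 9 between the factors) it meant a change of at most 1.5 times. Merging regions under 200 bp apart cannot change which genes lie within 1000 bp of a region, so that agreement was fixed in advance. The fold of overlap ranged from 1.39 to 4.98 for BLJ and from 1.42 to 4.98 for JKD. The fold for midpoints in genes ranged from 1.47 to 1.58 for BLJ and from 1.32 to 1.47 for JKD. For midpoints within 3000 bp of a gene it was 1.15 for each, where rotations already gave 85.7%. The log2 odds ratio for genes near both ranged from 0.96 to 4.91. Lists passing for BLJ and JKD, 1 each as reported, became 4 and 3 with the denser 50% of each list, 2 and 3 at an IDR at or below 0.1, 0 and 2 at an IDR at or below 0.05 (3 and 5 at an unadjusted p under 0.05) and 0 and 0 within 3000 bp of the gene (3 and 2 unadjusted). Without list members of other kinds they stayed at 1 each. JKD also moved to 2 for overlap with the gene itself. The cause was not tested. Lists differing between the factors rose from 0 to 3 and 6 at the IDR limits of 0.1 and 0.05, always with more members near JKD. All genes were split the same way (6401 near JKD alone and 4023 near BLJ alone at 0.1, 5067 and 2027 at 0.05), and against that split 0 lists passed, with NAC (exact p = 0.0186) and AP2/ERF (0.0239) under an unadjusted 0.05 at 0.1. The JKD log2 density difference of 0.06 fell to 0.000788 (permutation p = 0.687) relative to regions of like width, since shared regions are wider. Each density value alone gave 0.0649 to 0.172 for BLJ and 0.0552 to 0.0674 for JKD. The AP2/ERF median for BLJ turned from above to just below that of all genes with the first-listed value (each value alone gave 65.0 to 92.3, and the cause was not tested). Among single lists and genes, 659 values were the same and 61 genes' values moved (each losing its region). Values of lists passed newly in 11 cases and no longer passed in 4, where a list counts once per factor and setting, so the same list recurs. No paired analysis was possible because the lists were made on both replicates together and the density values carry no replicate number, and for the same reason no list could be rebuilt without a replicate. Motif results, windows around start sites and removal of transposable element genes were not run. Depth is unknown, so what it limits was not tested, and 8.21% of BLJ and 17.7% of JKD regions had an IDR at or below 0.05.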

Other observations

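The groups and tests in this part were chosen after the lists were seen. Of 81 gene families taken from shared symbols with at least 15 members, random lists of like gene length left 6 passing for BLJ and 5 for JKD (permutation, adjusted p under 0.05 over 81 families and both factors), 4 of them in both, all listed less often, and 3 of the 4 are described here. Beta-glucosidase genes (BGLU), which include enzymes of the endoplasmic reticulum bodies, had 23 and 22 of 40 (57.5% and 55.0%, where matched lists averaged 88.5% for BLJ and 84.7% for JKD). Serine carboxypeptidase-like genes (SCPL) had 69.4% and 63.3% of 49, against the same 88.5% and 84.7%. UMAMIT transporters of amino acids had 66.7% and 57.1% of 42, against 87.2% and 83.2%. Random lists drew genes singly. Family members that lie side by side can share a region or lack one together, which can make these p-values too small. BLJ alone passed for MYB (69.8% of 116 against 81.7%, adjusted permutation p = 0.0259, 0.227 for JKD) and for receptor-like proteins (RLP, 71.2% of 52 against 87.0%, 0.0295, 0.966 for JKD), and JKD alone for the small cysteine-rich LCR genes (36.2% of 80 against 56.0%, 0.0162, 0.486 for BLJ). Whether these 3 differ between the factors was not tested.

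Regions also overlapped genes that encode no protein. tRNA genes were overlapped in 56.3% of 625 cases by BLJ and 53.6% by JKD regions, with a median length of 73 bp. Long non-coding RNA genes gave 39.8% and 39.2% of 3480, miRNA genes 19.0% and 19.0% of 326, snoRNA genes 34.1% and 42.2% of 287 and snRNA genes 45.1% and 41.5% of 82. Pseudogenes gave 9.78% and 7.43% of 3917 with a median length of 2043 bp, close to the 2078 bp of protein-coding genes, of which 71.0% and 65.3% were overlapped. Transcribed pseudogenes gave 25.5% and 24.9% of 926. The shares of these classes were not set against rotations. How well reads of 50 bp can be placed in each class was not examined, so the shares do not compare binding between classes.

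A stretch of chromosome 2 that carries a copy of much of the mitochondrial genome formed the longest block, 191 kb (3297860 to 3488452). JKD regions covered 95.2% of it with densities of 0.95 and 2.33 times the genome-wide means, and BLJ regions covered 11.8% with 1.18 and 2.43 times. In the JKD list only the second-listed value was thus raised. Several JKD regions there stood at that list's highest IDR, 0.339, such as 3297860 to 3315335 (densities 0.933 and 3.11). Others were as low as 0.000332.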
